A study of Homo sapiens and Mus musculus with 25 samples.

How the data were processed

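Chromatin was profiled by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around its target, which is then sequenced. The human libraries came from CT27, an established human trophoblast stem cell (hTSC) line kept in its stem state, either as control cells or after knockdown of PRMT1. PRMT1 is the main enzyme that places asymmetric dimethylation on arginine, including H4R3me2a at arginine 3 of histone H4. The antibodies were raised against PRMT1, H4R3me2a and the C-terminal domain of the largest subunit of RNA polymerase II, with IgG as the control antibody. The mouse libraries came from ectoplacental cones (EPC), the trophoblast tissue above the early embryo, dissected from CD1 mice at embryonic day 7.5 and pooled. Reads were paired and 101 bp long, per the labels' protocols.

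Each of the 8 deposited files was a consensus peak list of 1 antibody in 1 group, giving the position of each peak and pooling all libraries of that group. The score column that the authors deposited was 0 in every line, so it held no peak height, fold enrichment or p-value. Human positions were on hg38 and mouse positions on mm10, per the submitters' processing notes. The aligner, the peak caller, its threshold, the use made of the IgG libraries and the rule that made a peak a consensus peak were not given in the sources used here. Lists were matched to groups by the antibody and condition in their names. The control PRMT1 list names no condition and was taken as control because the knockdown list is named separately. The mouse histone list is named with the residues transposed, and was taken as H4R3me2a because the labels give no other mouse histone mark. No read counts or coverage were used, so the depth of each library was unknown. The number of peaks in a list depends on that depth as well as on the chromatin, and no scaling between lists was possible.

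Because replicates were pooled in each list, no value carries a spread between replicates, and no test compares conditions across replicates. Percentages have exact (Clopper-Pearson) 95% confidence intervals, and ratios of peak numbers have intervals for counting error. Peaks and genes are not independent replicates, so all p-values describe the lists, not the conditions.

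A peak was shared when it overlapped a peak of the other list by at least 1 bp. Each overlap was set against 1000 random placements of the other list, with peak lengths and chromosomes kept. This is a permutation of peak positions, whose two-sided p cannot fall below 0.002. The assembly's gaps were not masked, as no genome sequence was used. A gene had a peak when a peak lay within 1 kb of either annotated end of the gene, for 19974 protein-coding genes of the RefSeq annotation of GRCh38.p14. The planned window was 1 kb around transcription starts, but the gene table gave no strand. For 563 genes with an annotated divergent transcript within 5 kb, the start could be told from the far end. Of these, 76 had a control PRMT1 peak at the start and 2 at the far end. The corresponding numbers were 293 and 41 for H4R3me2a and 431 and 50 for RNA polymerase II. Where a gene had several peaks, the width of the widest is given, so widths in 2 lists can belong to different ends of the gene. Exons and introns were not used here. No mouse genes were used, so the planned gene-based mouse comparisons and the sharing of genes between human and mouse were replaced by peak overlap or left out, with the mouse-only gene lists.

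Co-occupancy and missing peaks were tested with two-sided Fisher's exact tests, with p-values below 1e-300 given as that floor. Matched odds ratios used the Mantel-Haenszel method over 5 groups of control width of the peak tested as missing. Widths of kept and missing control peaks were compared by permutation with 100000 resamples. Fixed before the data were examined were 14 human gene lists, the designs, the first set of alternative settings and the rule for named genes. The lists covered trophoblast stem state, syncytiotrophoblast, extravillous trophoblast, cell cycle, p53 targets, arginine methylation, interferon response, immediate early genes, pluripotency, neural genes, other cell types (mesoderm, endoderm, blood and stroma), ribosomal proteins, replication-dependent histones and the respiratory chain. Each list was tested for control peaks against all other coding genes, and among genes with a control peak for absence from the knockdown list. Fisher p-values were adjusted by Benjamini-Hochberg over the 14 lists for each antibody, with a threshold of 0.05. Missing peaks of each list were also set against 10000 random lists matched on 5 groups of control peak width. These lists were drawn with replacement from the genes with a control peak.

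Named genes were chosen per human antibody by peak width, as no score was usable. They were the 10 genes with the widest control peak and none after knockdown, the 5 widest with a peak in both lists and the 5 widest in the knockdown list alone. Added to these were the 5 genes with the highest summed ranks for PRMT1 and H4R3me2a, up to 4 members of each list past the threshold, the PRMT1 gene and 11 trophoblast and growth genes. Peaks on the mitochondrial genome, the Y chromosome and unplaced sequences were not named. Genes named outside the rule, chosen after their values were seen, are the examples given for each gene list, the RNA polymerase II intervals above 10 kb and the non-coding genes.

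Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 were used. Overlap counts were checked with bedtools 2.31.1, which gave the same 23873 shared control H4R3me2a peaks. Tests on simulated lists recovered a planted overlap of 42.08% as 42.1% over 5000 peaks, 200 of 200 planted gene-end peaks among 19974 genes and a planted odds ratio of 5 as 5.02. In a simulation with no effect but unequal widths, the crude odds ratio was 0.245 and the matched one 0.901. Of 50 pairs of unrelated simulated lists, 1 passed the placement test. Alternatives covered the window, the overlap rule, merging of nearby peaks, chromosomes, peak width, the background genes and matching.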

Results

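CUT&RUN peaks for PRMT1, H4R3me2a and RNA polymerase II were compared between control and PRMT1-knockdown CT27 hTSC, and PRMT1 and H4R3me2a peaks were compared in mouse EPC. The 25 libraries comprised 19 human and 6 mouse ones. PRMT1 was profiled in 2 control and 3 knockdown libraries, H4R3me2a in 3 and 3, and RNA polymerase II in 2 and 2. The mouse EPC had 2 libraries each for PRMT1 and H4R3me2a. The remaining 6 libraries were IgG controls, for which no list was used here. Each of the 8 peak lists pooled the libraries of its group, so no spread between replicates could be given and depth was unknown. Numbers of peaks and of genes below are therefore properties of the lists.

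The first comparison asked where PRMT1 lay in control hTSC and whether its peaks were present after its knockdown. At the PRMT1 gene itself (chr19:49676153-49688447, hg38), the control list had a PRMT1 peak of 1265 bp over the gene end at chr19:49675853-49677117, and the knockdown list had none. The widest control PRMT1 peak at coding genes, 2696 bp at chr1:149885689-149888384, was shared by the histone genes H2BC21, H2AC20 and H2AC21 and was not in the knockdown list. Peaks of 2483 bp at HEXIM1, an inhibitor of the elongation kinase P-TEFb, of 2143 bp at the ribosomal protein gene RPL13A and of 2004 bp at the deubiquitinase gene USP48 were likewise missing after knockdown. In all, 1765 coding genes had a control PRMT1 peak at a gene end and 11 had one after knockdown.

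A control PRMT1 peak of 2375 bp at chr19:45404088-45406462 covered one end of PPP1R13L, which encodes an inhibitor of p53, and lay within 1 kb of POLR1G, which encodes a subunit of RNA polymerase I. Peaks of 2158 bp at LASP1 and 2003 bp at PLXDC1 on chromosome 17 also lay beside tRNA genes for cysteine. The 8 genes with a peak in both lists included ZNF687 (1179 bp in control and 310 bp after knockdown), CDCA3 and USP5, which share a peak (1070 and 386 bp), and CEP170 and SDCCAG8, which share another (989 and 449 bp). The DNA repair gene ERCC1 counted among them, but its 244 bp knockdown peak at chr19:45450983-45451226 lay at the other end of the gene from its control peak. The histone genes H2BC11 and H2AC11 shared a control peak of 909 bp and a knockdown peak of 241 bp that did not overlap it. Only ZSCAN22 (230 bp), CMTM3 (219 bp) and DELE1 (204 bp) had a peak in the knockdown list alone.

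The control PRMT1 list held 3482 peaks over 1.89 Mb, and the knockdown list held 308 over 0.139 Mb, a ratio of 11.3 in number (95% CI for counting error 10.1 to 12.7). A knockdown peak overlapped 5.40% of control peaks (95% CI 4.67 to 6.20%), against a mean of 0.166% for random placements (two-sided placement permutation p = 0.002, the smallest possible). Of the knockdown peaks, 60.4% overlapped a control peak. Kept control peaks had a median width of 502.5 bp against 462 bp for missing ones (two-sided permutation test, p = 0.0389). Gene ends held 39.4% of control PRMT1 peaks, against 3.08% of placed peaks (placement permutation p = 0.002), and 2.60% of knockdown peaks, against 2.50% of placed peaks (p = 1). A knockdown peak overlapped 0.364% of the control peaks at gene ends (95% CI 0.118 to 0.848%), 3.62% of those within genes and 11.9% of those elsewhere (95% CI 10.2 to 13.9%). In a split made after the results were seen, 28.3% of the 258 control peaks over 500 kb from any annotated gene were overlapped. Of the nearer control peaks, 3.28% were. With control and knockdown peaks limited to those at least as wide as the control median, the ratio in number was 18.98, and 978 genes had PRMT1 in control alone when the control list alone was so limited. Counting peaks anywhere in a gene, 42 genes had PRMT1 in both lists and 17 in the knockdown list alone, and within 3 kb of gene ends lay 5.84% of knockdown peaks. Of knockdown peaks at or above their median width, 1.30% lay at gene ends.

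Among the gene groups, PRMT1 peaks were most frequent at replication-dependent histone genes, which supply the histones of newly copied DNA. In control cells 38 of 69 had a PRMT1 peak, from 22 separate peaks, against 8.68% of other genes (odds ratio 12.9, 95% CI 8.01 to 20.8, Fisher's exact test adjusted over 14 lists, p = 2.28e-21). Besides the H2BC21 peak, these included 1958 bp at H2BC18, 1549 bp shared by H3C4, H2AC7 and H2BC7, and 1230 bp at the linker histone gene H1-2. The p53 target list had 7 of 20 genes with PRMT1 (odds ratio 5.57, adjusted Fisher p = 0.00596), among them MDM2 (1255 bp), the ubiquitin ligase that degrades p53, PLK3 (1075 bp), RRM2B (862 bp) and TP53I3 (450 bp). Ribosomal protein genes had 17 of 83 (odds ratio 2.67, adjusted Fisher p = 0.00596), with RPL3 (1454 bp), RPLP0 (1386 bp) and RPL23A (1063 bp) after RPL13A. When only the 11330 genes with a peak in at least 1 human list served as background, histone genes stayed past the threshold (odds ratio 9.13, adjusted Fisher p = 1.90e-15), whereas p53 targets (odds ratio 3.46, adjusted p = 0.101) and ribosomal protein genes (odds ratio 1.42, adjusted p = 0.770) did not.

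No other list passed the threshold for control PRMT1 peaks. The trophoblast stem state list had 6 of 32 genes (adjusted Fisher p = 0.136), namely LRP2, GATA2, GRHL2, TEAD4, KRT18 and VGLL1. The syncytiotrophoblast list, for the fused hormone-secreting layer, had 4 of 32 (INHA, ERVFRD-1, TBX3 and DLX3; adjusted Fisher p = 0.734), and the extravillous list, for the invasive lineage, had 2 of 24 (ASCL2 and TCF7L2; adjusted p = 1). Cell cycle genes had 8 of 42, including CDK1, CDK2, CDC20 and MYC (adjusted Fisher p = 0.1004), and immediate early genes had 6 of 29, including FOS, FOSB, JUN and EGR1 (adjusted p = 0.107). The arginine methylation list had 3 of 16 (PRMT1, JMJD6 and FBL; adjusted Fisher p = 0.285), the interferon list 1 of 25 (RIGI; adjusted p = 0.841), the pluripotency list 1 of 16 (LIN28A; adjusted p = 1) and the respiratory chain list 8 of 82 (adjusted p = 0.841). None of 24 neural genes (adjusted Fisher p = 0.413) and none of 34 genes of other cell types (adjusted p = 0.140) had a PRMT1 peak. Every list member with a control PRMT1 peak lacked one after knockdown, except H2BC11 and H2AC11, and no list passed the test for missing peaks (histones adjusted Fisher p = 0.163).

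The second comparison asked whether the histone mark that PRMT1 deposits was present at the same places after knockdown. H4R3me2a was found at the ends of 7852 coding genes in control cells and 6551 after knockdown, of which 5395 were shared, 2457 were in control alone and 1156 were in knockdown alone. The widest control H4R3me2a peaks with none at the gene ends after knockdown were at MPZL1 (6182 bp), FXYD4 (4806 bp), C10orf95 (4490 bp), ERVH48-1, a gene of retroviral origin (4430 bp), SLC9A5 (4349 bp), ARID5B (4078 bp) and USP47 (3855 bp). LOC124904579 (3669 bp), ZBTB1 (3640 bp) and CPXM2 (3488 bp) followed. Peaks of this mark were still present inside the gene after knockdown at MPZL1, ERVH48-1, SLC9A5, ARID5B, USP47, ZBTB1 and CPXM2.

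The widest H4R3me2a peak at genes with the mark in both lists spanned 7211 bp at chr17:75978235-75985445, by ACOX1, the first enzyme of peroxisomal beta-oxidation, and TEN1, where the knockdown peak was 867 bp. CGN, which encodes the tight junction protein cingulin, had 6212 bp in control and 3445 bp after knockdown, TUFT1 had 5937 and 2352 bp, and the polarity gene PARD6B had 5841 and 671 bp. The genes with the widest knockdown peak and none in control were PCBD2 (2598 bp), BAP1 and PHF7 (2131 bp, shared), and AIRIM and CDCA8 (1939 bp, shared). At the PRMT1 gene the mark was present in both lists, at 1155 bp in control and 1659 bp after knockdown. Among the trophoblast genes, TFAP2C had 527 and 740 bp and ELF5 1165 and 891 bp, while TEAD4 had 595 bp in control and none at its ends after knockdown. MYC had 3985 and 500 bp, and ASCL2 none in control and 513 bp after knockdown. TP63, GCM1, CGA, CCND1 and HLA-G had no H4R3me2a peak at their ends in either list.

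The control H4R3me2a list held 55725 peaks over 53.1 Mb and the knockdown list 27732 over 20.5 Mb, a ratio of 2.01 in number (95% CI 1.98 to 2.04). A knockdown peak overlapped 42.8% of control peaks (95% CI 42.4 to 43.3%; 1.70% for placements, permutation p = 0.002), and 89.1% of knockdown peaks overlapped a control peak. Gene ends held 11.9% of control and 20.2% of knockdown peaks, and 61.2% of the control peaks at gene ends were kept, against 39.6% within genes and 41.2% elsewhere. Kept control peaks were wider, with a median of 1165 bp against 568 bp for missing ones (two-sided permutation test, p = 1e-05, the smallest possible). Across 5 equal groups by control width, the kept share rose from 12.0% in the narrowest to 85.3% in the widest. With the control list limited to peaks at or above its median width and the knockdown list left whole, 842 genes had the mark in control alone, 3536 in both and 3015 in knockdown alone, and 66.5% of those control peaks were overlapped. Of all control peaks, 26.4% were covered over at least 50% of their width, 8748 genes had the mark in both lists when gene bodies were counted, and within 3 kb of gene ends lay 21.3% of control peaks.

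**Figure D1:**
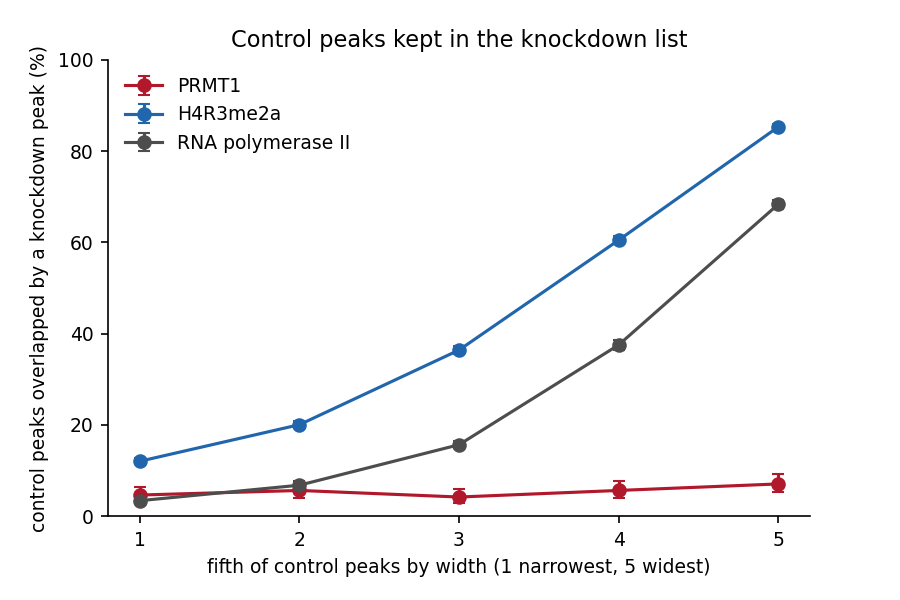
Percent of control peaks overlapped by a knockdown peak (y axis) for 5 equal groups of control peak width, narrowest to widest (x axis), with exact 95% confidence intervals, for PRMT1, H4R3me2a and RNA polymerase II. The kept share rose from 12.0 to 85.3% for H4R3me2a and from 3.37 to 68.3% for RNA polymerase II, and lay between 4.16 and 7.03% for PRMT1.

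H4R3me2a marked trophoblast stem state genes more often than other genes, at 23 of 32 (odds ratio 3.95, adjusted Fisher p = 0.00101), including KRT7 (3209 bp in control and 2046 bp after knockdown), EPCAM (2904 and 1654 bp) and GATA3 (2556 and 675 bp). The mark was also more frequent at p53 targets (16 of 20, adjusted Fisher p = 0.00103), histone genes (50 of 69, adjusted p = 4.72e-07), respiratory chain genes (50 of 82, adjusted p = 6.50e-04), ribosomal protein genes (46 of 83, adjusted p = 0.00649) and immediate early genes (18 of 29, adjusted p = 0.0361). It was less frequent at neural genes (2 of 24, SLC17A7 and TUBB3; adjusted Fisher p = 0.00289) and genes of other cell types (4 of 34, COL1A1, TBX6, GATA1 and HBA1; adjusted p = 0.00179). None of these 8 lists passed the threshold against the 11330 genes with a peak in at least 1 human list (stem state odds ratio 2.04, adjusted Fisher p = 0.438). Of that background, 7852 genes had the mark in control, so it was itself selected in part on the mark. The remaining lists did not pass against all other genes, with syncytiotrophoblast at 14 of 32 (adjusted Fisher p = 0.692), extravillous 9 of 24 (adjusted p = 1), cell cycle 20 of 42 (adjusted p = 0.347), arginine methylation 10 of 16 (adjusted p = 0.113), interferon 11 of 25 (adjusted p = 0.737) and pluripotency 3 of 16 (adjusted p = 0.174).

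After knockdown, H4R3me2a was absent from 5 of the 23 stem state genes that had it (MSX2, YAP1, TEAD4, KLF5 and VGLL1), and CDX2, ETS2, PEG10 and SKP2 had it in the knockdown list alone. It was absent from 6 of 14 syncytiotrophoblast, 3 of 9 extravillous, 4 of 20 cell cycle, 3 of 16 p53 target, 3 of 10 arginine methylation, 6 of 11 interferon and 4 of 18 immediate early genes. The counts were 1 of 3 pluripotency, 1 of 2 neural, 3 of 4 other cell type, 18 of 46 ribosomal protein, 7 of 50 histone and 19 of 50 respiratory chain genes. No list differed from other marked genes past the threshold, with histones closest (odds ratio 0.356, adjusted Fisher p = 0.119).

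The third comparison asked where RNA polymerase II lay before and after PRMT1 knockdown. GATA3, a transcription factor of trophoblast cells, had the widest control interval at a coding gene, 29346 bp at chr10:8048873-8078218, and its widest knockdown interval was 10739 bp. NUAK2, a kinase gene, had 25277 and 4960 bp, NABP1, for a single-stranded DNA binding protein, 20431 and 9433 bp, EZR, for the membrane linker ezrin, 16895 and 2991 bp, and the keratin gene KRT8 15615 and 13980 bp. All knockdown intervals together covered 82.4% of the control interval at GATA3, 51.1% at NUAK2, 75.7% at NABP1, 59.2% at EZR and 89.5% at KRT8. The widest control peaks at genes with none at their ends after knockdown were at TRPV2 (8922 bp), TNFRSF21 (6297 bp), PKP2, a desmosome gene (6222 bp), ACTR6 (5219 bp), SLC7A2 (5080 bp), ATG9B (4847 bp), TP53BP2 (4841 bp), SPG7 (4839 bp), PEBP1 (4613 bp) and ZAN (4591 bp). Peaks were still present inside the gene after knockdown at TNFRSF21, PKP2, ACTR6, SLC7A2, PEBP1 and ZAN. TUBA1C (1040 bp), CD248 (1031 bp), SLC10A1 (996 bp) and the overlapping genes IGF2 and INS-IGF2 (853 bp) had the widest peaks in the knockdown list alone.

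**Figure D2:**
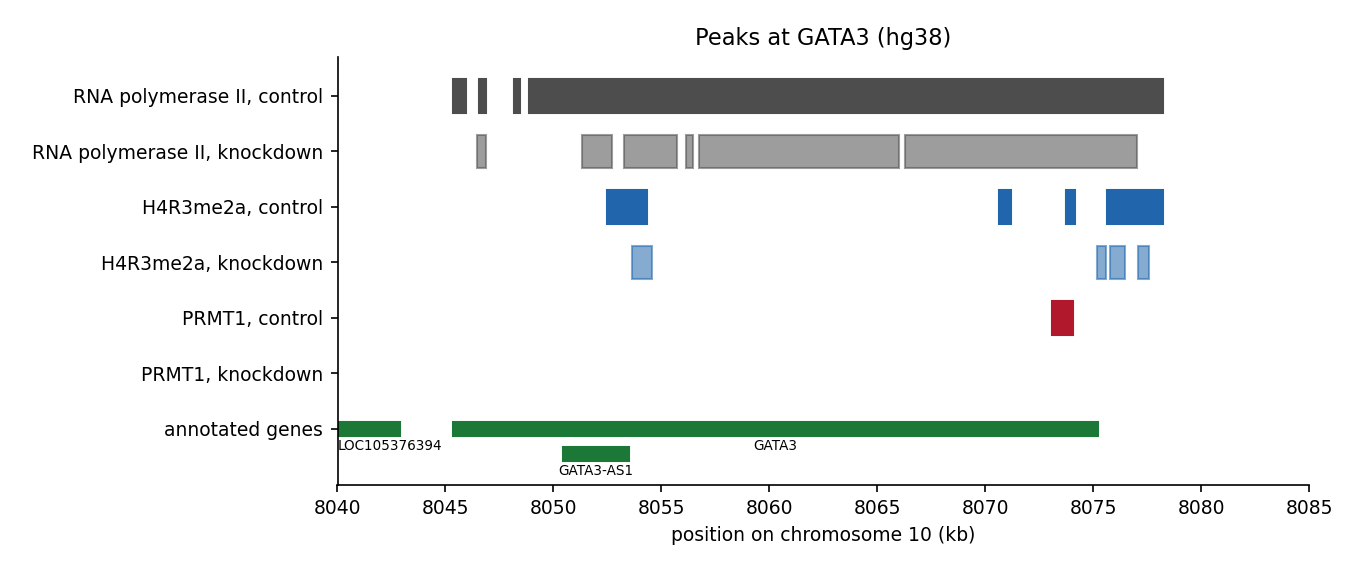
Map of the GATA3 region on chromosome 10 (x axis, hg38 position) with the annotated genes and the peaks of each human list as boxes, 1 line per list. The 29346 bp control RNA polymerase II interval was split into several intervals after knockdown, and the single PRMT1 peak, at 8073090 to 8074064, was in the control list alone.

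At the PRMT1 gene, the widest RNA polymerase II peak was 4205 bp in control and 1609 bp after knockdown. TFAP2C had 3438 and 714 bp, ELF5 940 and 306 bp, ASCL2 3159 and 912 bp, CCND1 1740 and 591 bp, and MYC 3689 and 595 bp. CGA, which encodes the alpha chain of chorionic gonadotropin, had 5682 and 3866 bp. TEAD4 had 2038 bp in control and none at its ends after knockdown, although peaks lay within the gene in both lists. TP63 and GCM1 had no peak at their ends and peaks within the gene in both lists, and HLA-G had none at its ends or within it.

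In all, 10404 coding genes had RNA polymerase II at a gene end in control cells and 5800 after knockdown, of which 5754 were shared, 4650 were in control alone and 46 in knockdown alone. The share missing was 44.7% (95% CI 43.7 to 45.7%). The control list held 36559 peaks over 36.2 Mb and the knockdown list 11183 over 7.76 Mb, a ratio of 3.27 in number (95% CI 3.20 to 3.34), and 5.67 among peaks at least as wide as the control median. A knockdown peak overlapped 26.3% of control peaks (95% CI 25.9 to 26.8%; 0.774% for placements, permutation p = 0.002), and 93.4% of knockdown peaks overlapped a control peak. Gene ends held 24.9% of control and 43.5% of knockdown peaks, and 48.7% of control peaks at gene ends were kept, against 20.0% of those within genes and 17.4% elsewhere. Kept peaks had a median width of 1404 bp against 619 bp for missing ones (permutation p = 1e-05, the smallest possible). With the control list limited to peaks at or above its median width, 2772 genes had RNA polymerase II in control alone and 384 in knockdown alone, and 45.9% of those control peaks were overlapped. As many of the widest control peaks as the knockdown list holds were overlapped at 59.8%, and 10.5% of all control peaks were covered over at least 50% of their width.

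Control RNA polymerase II intervals above 10 kb numbered 33, and 32 of them overlapped a knockdown interval, the exception being a 10204 bp interval at HNRNPU, which encodes a nuclear RNA-binding protein. Across the 33, knockdown intervals covered a median of 75.7% of the control width. The widest, 35041 bp at chr19:53651370-53686410, held no protein-coding gene and covered LOC107985342 and 9 microRNA genes, among them MIR512-1, MIR498 and MIR515-1. Knockdown intervals, 9 in number, covered 92.4% of it, and neither list had an H4R3me2a peak within it. Coverage was 97.7% at GATA2 (15034 bp), 91.5% at the actin gene ACTB (15332 bp), 90.1% at the non-coding RNA gene MALAT1 (14364 bp) and 82.4% at GATA3, and lower at CLIC4 (14651 bp, 14.1%) and the actin cross-linker gene ACTN1 (11279 bp, 19.1%).

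**Figure D3:**
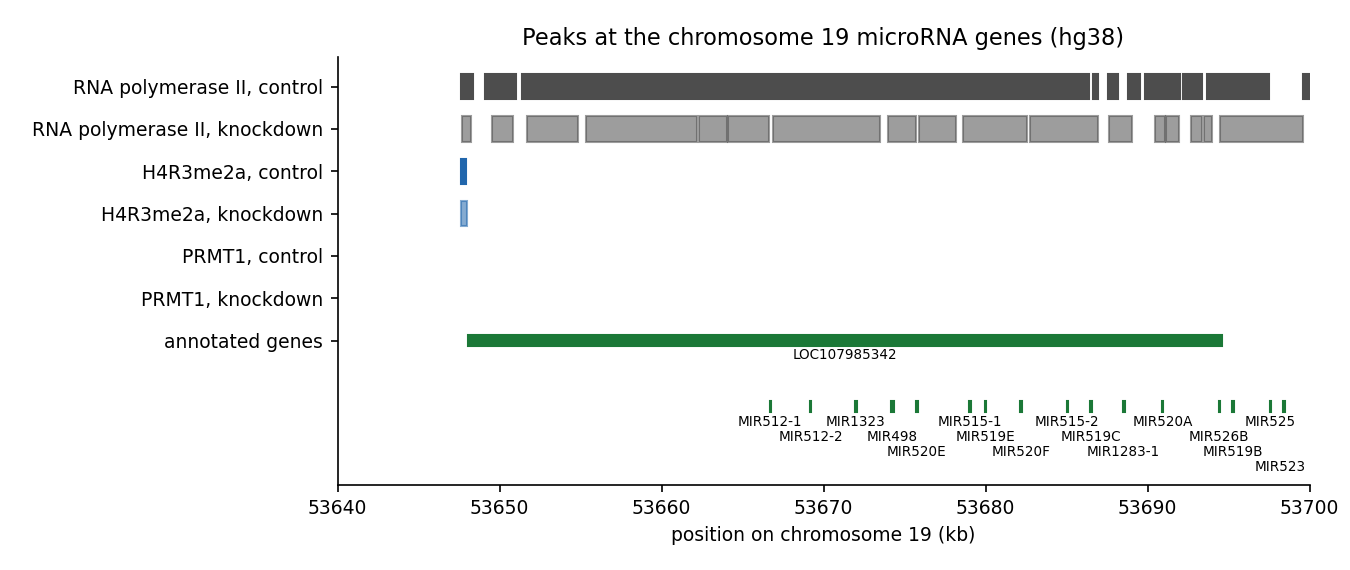
Map of the microRNA cluster on chromosome 19 (x axis, hg38 position) with annotated genes and the peaks of each human list as boxes, 1 line per list. The 35041 bp control RNA polymerase II interval was covered to 92.4% by 9 knockdown intervals, and no H4R3me2a peak lay within it.

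RNA polymerase II was present in control cells at 26 of 32 stem state genes (odds ratio 3.99, adjusted Fisher p = 0.00167), 40 of 42 cell cycle genes (odds ratio 18.5, adjusted p = 1.07e-08), 18 of 20 p53 targets (adjusted p = 8.52e-04) and 14 of 16 arginine methylation genes (adjusted p = 0.00653). It was also more frequent at immediate early genes (26 of 29, adjusted Fisher p = 4.43e-05), ribosomal protein genes (81 of 83, adjusted p = 2.08e-19), histone genes (59 of 69, adjusted p = 2.57e-08) and respiratory chain genes (68 of 82, adjusted p = 2.57e-08). Genes of other cell types (4 of 34, CDH5, GATA6, COL1A1 and TBX6; adjusted Fisher p = 2.56e-06), neural genes (1 of 24, TUBB3; adjusted p = 2.04e-06) and pluripotency genes (3 of 16, ZFP42, LIN28A and SALL4; adjusted p = 0.0130) had it less often. None of these 11 lists passed the threshold against the 11330 genes with a peak in at least 1 human list (ribosomal proteins odds ratio 7.26, adjusted Fisher p = 0.104). Of that background, 10404 genes had a control RNA polymerase II peak, which left little room for a short list to differ. Cell cycle genes failed there with an odds ratio of 7.24 (adjusted Fisher p = 0.207). Syncytiotrophoblast (16 of 32, adjusted Fisher p = 0.927), extravillous (12 of 24, adjusted p = 0.927) and interferon genes (13 of 25, adjusted p = 1) did not differ from other genes past the threshold.

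After knockdown, ribosomal protein genes had the smallest share of missing RNA polymerase II peaks among lists with more than 1 control gene, with 5 of 81 missing (RPL14, RPL29, RPL3L, RPS21 and RPS28; odds ratio 0.0804, adjusted Fisher p = 2.38e-13). Histone genes lacked 4 of 59 (H2AC18, H2AC19, H4C9 and H4C15; odds ratio 0.0892, adjusted Fisher p = 1.10e-09), and immediate early genes 3 of 26 (ATF3, EGR3 and KLF2; odds ratio 0.161, adjusted p = 0.00237). FOS kept an interval of 7824 bp from 8556 bp, RPL3 11705 bp from 12150 bp and H2BC21 3440 bp from 4389 bp. Against random lists with control peaks of the same widths (permutation within 5 width groups), ribosomal protein genes (6.17% missing against 22.3%, adjusted p = 0.00560) and histone genes (6.78% against 19.9%, adjusted p = 0.0406) stayed past the threshold and immediate early genes (11.5% against 24.0%, adjusted p = 0.453) did not. Against random lists matched on gene length and peak width together, no list passed the threshold, with 16.7% missing for ribosomal protein genes (adjusted permutation p = 0.0728) and 13.99% for histone genes (adjusted p = 0.526), whose 59 genes rested on 34 control intervals.

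The stem state list lacked 10 of 26 genes after knockdown (LRP2, ITGA6, FGFR2, YAP1, TEAD4, KRT7, KLF5, SPINT1, ETS2 and VGLL1; adjusted Fisher p = 0.727) and had peaks at the gene ends in both lists at GATA2, GATA3, TFAP2A, TFAP2C, ELF5, KRT8, KRT18 and CDH1 among others. Syncytiotrophoblast genes lacked 6 of 16, including CYP19A1, the aromatase gene, and HSD11B2 (adjusted Fisher p = 0.727), and extravillous genes 8 of 12, including FN1, ITGA1, ITGA5 and SNAI1 (adjusted p = 0.353). Cell cycle genes lacked 15 of 40, among them MCM2, MCM5, MCM6, PLK1, BUB1, MKI67 and TOP2A (adjusted Fisher p = 0.664). The p53 targets lacked 4 of 18 (BAX, BBC3, PHLDA3 and ZMAT3; adjusted Fisher p = 0.169), and the arginine methylation list 6 of 14 (PRMT2, PRMT3, PRMT6, PRMT7, PRMT9 and WDR77; adjusted p = 1). The interferon list lacked 4 of 13 (adjusted Fisher p = 0.664), respiratory chain genes 26 of 68 (adjusted p = 0.656), pluripotency genes 2 of 3 (adjusted p = 0.727), the neural list 0 of 1 (adjusted p = 1) and other cell types 4 of 4 (adjusted p = 0.140).

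**Figure D4:**
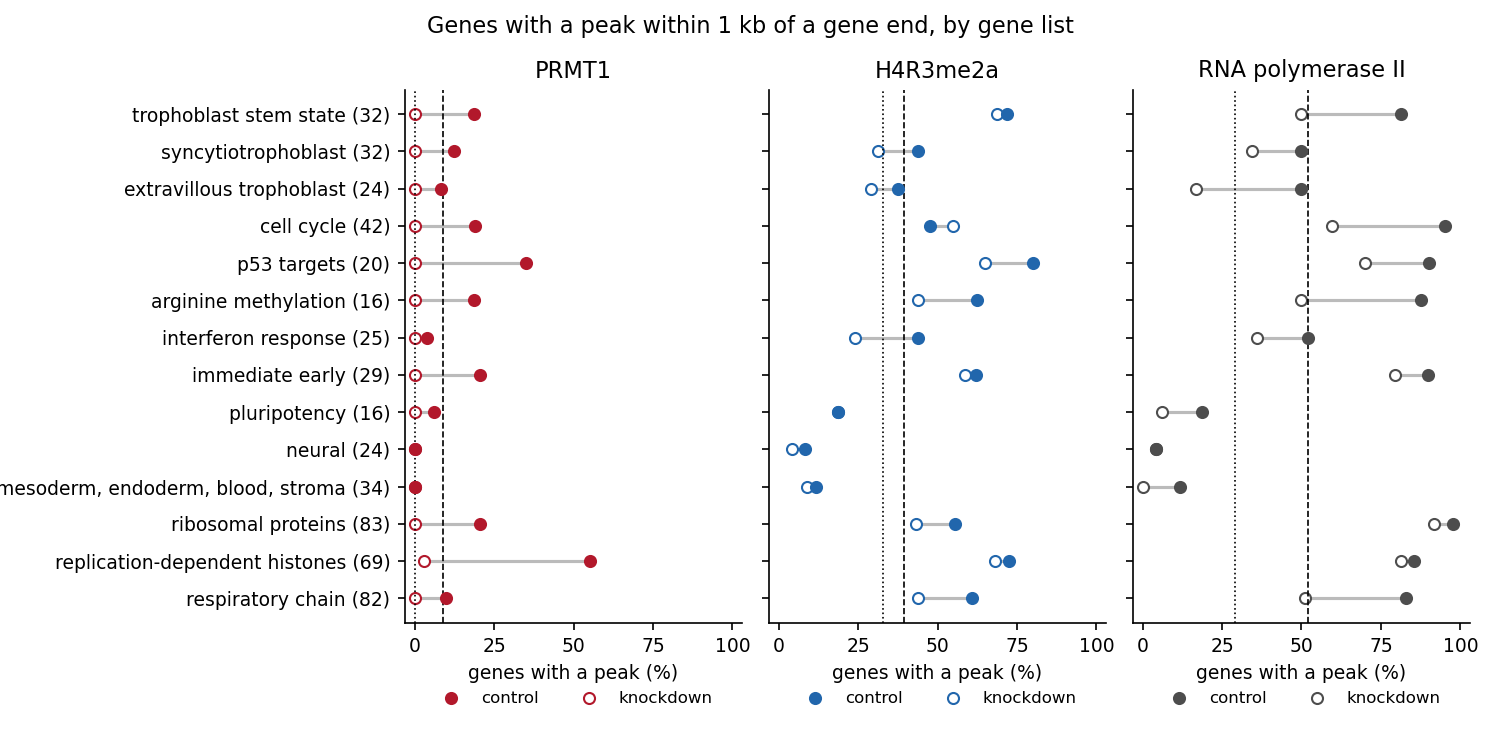
Percent of genes with a peak within 1 kb of a gene end (x axis) for the 14 gene lists (y axis), 1 panel per antibody. Numbers in brackets are the genes of each list. Filled dots show control and open dots knockdown, joined by a line. Dashed and dotted vertical lines give the percent of all coding genes in control and knockdown. Control PRMT1 peaks were most frequent at histone genes, at 55.1%. RNA polymerase II was at 97.6% of ribosomal protein genes in control and 91.6% after knockdown.

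The fourth comparison asked whether PRMT1, its mark and RNA polymerase II were found at the same genes in control hTSC. PPP1R13L, POLR1G and ERCC1, around a shared PRMT1 peak of 2375 bp and H4R3me2a peak of 3807 bp, ranked highest for PRMT1 and H4R3me2a together, followed by LOC124904276 and RBM15, which share peaks of 1393 and 4674 bp. Of the 1765 genes with PRMT1, 1590 (90.1%) also had H4R3me2a, where 694 would be shared by independent lists (odds ratio 17.3, 95% CI 14.8 to 20.3). RNA polymerase II was present at 1757 (99.5%) of the PRMT1 genes (odds ratio 243, 95% CI 121 to 487), and both at 1586 (89.9%). H4R3me2a and RNA polymerase II shared 7057 genes, where 4090 would be shared by independent lists (odds ratio 23.3, 95% CI 21.4 to 25.3). Each Fisher's exact p lay below the floor of 1e-300. With genes lacking any human peak left out, the odds ratio of RNA polymerase II and H4R3me2a turned to 0.347 (95% CI 0.288 to 0.420, Fisher p = 7.22e-34), since that background removes nearly all genes with neither. On it, the odds ratios were 4.79 for PRMT1 with H4R3me2a and 23.3 for PRMT1 with RNA polymerase II.

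By peaks, 77.9% of control PRMT1 peaks overlapped a control H4R3me2a peak (3.31% for placements) and 85.9% a control RNA polymerase II peak (2.40% for placements). The knockdown lists of H4R3me2a and RNA polymerase II overlapped 73.4 and 63.8% of the same control PRMT1 peaks (all placement permutation p = 0.002, the smallest possible). RNA polymerase II was present in control cells at 96.6% of genes with H4R3me2a in both lists, 75.1% of those with it in control alone, 91.9% of those with it after knockdown alone and 20.8% of those with neither.

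The last human comparison asked whether peaks were missing after knockdown at the genes PRMT1 had occupied. H4R3me2a was missing at 153 of the 1590 genes with both control peaks (9.62%) and at 2304 of 6262 marked genes without PRMT1 (36.8%), so it was missing less often where PRMT1 had been (odds ratio 0.183, 95% CI 0.154 to 0.218, Fisher's exact test p = 3.70e-113). RNA polymerase II was missing at 225 of 1757 PRMT1 genes (12.8%) and 4425 of 8647 others (51.2%; odds ratio 0.140, Fisher p = 1.52e-214). It was missing more often where H4R3me2a was missing, at 1154 of 1844 genes (62.6%), than where the mark was kept, at 1443 of 5213 (27.7%; odds ratio 4.37, 95% CI 3.91 to 4.89, Fisher p = 2.90e-153). Matching on control peak width gave odds ratios of 0.229 (95% CI 0.191 to 0.274), 0.252 (95% CI 0.215 to 0.295) and 3.40 (95% CI 3.00 to 3.85), of which the second moved by over 1.5 times. The width matched was that of H4R3me2a for the first and of RNA polymerase II for the other comparisons. H4R3me2a width was not matched in the third. It therefore cannot separate a link between mark and polymerase from narrow peaks of both antibodies going uncalled together.

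In mouse EPC, the question was whether PRMT1 and H4R3me2a lay at the same places in trophoblast tissue of the embryo. The widest PRMT1 peak, 2201 bp at chr5:25816289-25818489 (mm10), overlapped the widest H4R3me2a peak on the main chromosomes, 1740 bp at chr5:25816779-25818518. A PRMT1 peak of 1521 bp at chr6:117792983-117794503 and an H4R3me2a peak of 1224 bp at chr11:6648663-6649886 were also shared. Genes at these positions were not analysed here. The PRMT1 list held 14921 peaks with a median width of 132 bp and the H4R3me2a list 11860 with a median of 175 bp, 7 of them mitochondrial. An H4R3me2a peak overlapped 31.5% of PRMT1 peaks (4707; 95% CI 30.8 to 32.3%; 0.175% for placements), and a PRMT1 peak overlapped 38.3% of H4R3me2a peaks (4548; 95% CI 37.5 to 39.2%; 0.219% for placements), each with a placement p of 0.002, the smallest possible. The shared part of PRMT1 peaks rose from 15.1% in the narrowest of 5 equal width groups to 60.1% in the widest, and that of H4R3me2a peaks from 19.4 to 60.6%. Mouse and human shares were not compared, since the lists differ in species, number of peaks and width.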

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

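All tests in this part were chosen only after the results were seen, except the tests of the 14 lists for missing H4R3me2a. For ribosomal protein genes against lists matched on gene length and peak width together, the prediction was written before that comparison was run, but after the pattern was seen.

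Non-coding genes lay outside the comparisons of coding genes, and all 5 classes examined had control PRMT1 peaks at more genes than any of 100 random placements. Of 443 tRNA genes, 124 had a control PRMT1 peak within 1 kb of an end, where placements gave at most 6. Of 154 spliceosomal and other snRNA genes, 22 had one, where placements gave at most 4. The other classes were long non-coding RNA genes (527 of 18177, at most 141 in placements), microRNA genes (42 of 1911, at most 15) and snoRNA genes (19 of 1196, at most 12). After knockdown, 1 tRNA gene, 10 long non-coding RNA genes and 0 of the remaining classes had a PRMT1 peak. No explanation was weighed for these counts.

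All 3 knockdown lists held fewer peaks than the control lists. A lower sensitivity of the knockdown libraries predicts that narrow control peaks disappear first, and the kept share of H4R3me2a peaks was 73.3 percentage points higher in the widest than in the narrowest of 5 width groups (95% CI 72.4 to 74.2), with 65.0 points for RNA polymerase II (95% CI 63.8 to 66.1), which is consistent with it. For PRMT1, which had the largest ratio of control to knockdown peaks, kept peaks were wider by 40.5 bp in the median. The difference in kept share between its widest and narrowest groups was 2.43 points (95% CI -0.0218 to 4.89). That interval spans 0 and lies below the 10 points the explanation needed, so lower sensitivity and a loss of PRMT1 cannot be told apart there by width. Missing H4R3me2a peaks were not centred on the genes that PRMT1 occupied, with a width-matched odds ratio of 0.229 (95% CI 0.191 to 0.274) there. The lists hold no peak height, so a loss that leaves a peak called would not be seen, and width is not height. This test therefore cannot decide whether the mark was reduced most where PRMT1 had been. A broad loss of the mark and of polymerase after knockdown, weakest peaks first, would give the same dependence on width for these 2 antibodies, so it stays open beside a difference in depth or signal. The IgG libraries and read depths that could separate them were not used here.

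Of the 290 knockdown PRMT1 peaks on the numbered chromosomes and X, 115 (39.7%) lay over 500 kb from any annotated gene, outside the gene-based comparisons. In the control PRMT1 list 258 of 3458 peaks did, a smaller share (7.46%) but a larger number. Of the far knockdown peaks, 63.5% overlapped a control PRMT1 peak. On chromosome 1, 77 of the 115 knockdown ones lay between 122510989 and 125182738, and 185 of the 258 control ones between 122503653 and 125182731. The other human lists also had far peaks on this stretch. H4R3me2a had 33 in control and 17 after knockdown, and RNA polymerase II 34 and 30. To test background from repeated sequence, the far knockdown PRMT1 peaks were compared with the lists of the other antibodies. These overlapped 44.3% of them (51 of 115, 95% CI 35.1 to 53.9%). The nearer knockdown PRMT1 peaks overlapped these lists at 55.4% (97 of 175, 95% CI 47.7 to 62.9%). The nearer peaks included 23 packed between 143184902 and 143266788 of chromosome 1. Repeated sequence among the nearer peaks was not assessed, so this contrast cannot show whether sharing was particular to the far ones. Counted from the other lists, sharing with PRMT1 was more frequent at far peaks. A control PRMT1 peak overlapped 83.3% of the 60 far control H4R3me2a peaks, against 4.74% of nearer ones. For control RNA polymerase II the shares were 84.8% of 46 far peaks and 7.78% of nearer ones. The interval for the far knockdown PRMT1 peaks spans the 50% the explanation needed and lies above the 5% that would have excluded it. Background and PRMT1 binding at these sites therefore cannot be told apart from these lists.

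In all 14 lists, genes lacking H4R3me2a alone after knockdown were counted against genes lacking RNA polymerase II alone, and ribosomal protein and histone genes passed the threshold. Among 45 ribosomal protein genes with both control peaks, 17 lacked H4R3me2a alone and 0 lacked RNA polymerase II alone, against 673 and 1443 of the other genes (Fisher's exact test adjusted over 14 lists, p = 5.69e-08). Among 49 histone genes, 5 lacked H4R3me2a alone and 0 RNA polymerase II alone (adjusted Fisher p = 0.0246 against other genes). Within the histone list this difference between antibodies did not pass the threshold (exact McNemar p = 0.0625; 0.438 adjusted over the 14 lists). Both counts rest on the 0 genes lacking RNA polymerase II alone, so they largely restate that RNA polymerase II was kept there, and neither list passed the test for missing H4R3me2a (adjusted Fisher p = 0.652 and 0.119).

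For RNA polymerase II kept at ribosomal protein genes, 6.17% of control peaks were missing. Random lists matched on peak width lacked 22.3% (permutation p = 4e-04), which argues against wide peaks as the whole cause. Lists matched on gene length and width together lacked 16.7% (permutation p = 0.0052, and 0.0728 adjusted over the 14 lists). The adjusted value did not pass the threshold, so short genes with wide peaks stay open as a cause. Among the 45 ribosomal protein genes with both control peaks, 17 lacked H4R3me2a after knockdown and 0 lacked RNA polymerase II. By called peaks, this argues against retention of H4R3me2a as the whole cause at these genes. Of the ribosomal protein genes that kept RNA polymerase II, 46.1% had a knockdown H4R3me2a peak (35 of 76, 95% CI 34.5 to 57.9%). For other genes that kept it the share was 77.3% (4389 of 5678, 95% CI 76.2 to 78.4%). These shares did not require a control H4R3me2a peak, so their difference does not measure retention. A candidate explanation is a higher level of polymerase at these highly transcribed genes, which only a signal track could show. No expression level was used here.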

How the results depend on the processing

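Tests chosen after the data were seen were those on peaks at or above a median width, circular shifts, gene bodies, width matching, shared histone peaks and all mouse overlaps. Of 120 alternatives (66 planned, 54 added later) over 37 results, 92 kept their value or their direction and side of the threshold, 27 moved and 1 reversed. The results on widths of kept and missing peaks had no alternative. Some alternatives could not change a result, as the background of genes with a human peak left the missing-peak odds ratios at 0.183 and 4.37. Overlap shares counted as kept when still above placements, although that of RNA polymerase II ranged from 10.5 to 59.8%. The reversal was RNA polymerase II with H4R3me2a against genes with a human peak, 0.347, because that background removes genes with neither. The same background left 1 PRMT1, 0 H4R3me2a and 0 RNA polymerase II lists past the threshold. Of its 11330 genes, 10404 had a control RNA polymerase II peak, so for that antibody a short list had little room to differ. A 3 kb window gave 5 PRMT1 lists (including all 3), 11 genes with PRMT1 after knockdown alone, and gene-end shares of 47.4% (control PRMT1), 5.84% (knockdown PRMT1), 21.3 and 27.9% (H4R3me2a, control and knockdown) and 34.5 and 53.6% (RNA polymerase II), by its larger area. The window of 2 kb outside to 500 bp inside gave 6 PRMT1 genes after knockdown alone. Gene bodies gave 17 such genes, 42 with PRMT1 in both lists and 8748 with H4R3me2a in both. Limited to peaks at least as wide as the control median, control over knockdown was 18.98 for PRMT1 and 5.67 for RNA polymerase II. With such a limit on the control list alone, PRMT1 had 978 control-only genes, H4R3me2a 842 control-only, 3536 shared and 3015 knockdown-only, and RNA polymerase II 2772 control-only and 384 knockdown-only, since knockdown peaks then outlast their narrower control partners. Among peaks above each list's median width, gene-end shares became 42.2% (control PRMT1), 1.30% (knockdown PRMT1, within the interval of the value for all peaks), 11.0% (control H4R3me2a), and 34.9 and 51.6% (RNA polymerase II); the cause was not tested. The odds ratio of a missing H4R3me2a peak at PRMT1 genes ranged from 0.153 to 0.255. No paired analysis was possible because each list pools its replicates; for the same reason leaving out replicates and requiring support from 2 replicates were not run, nor were mouse gene comparisons. Unknown depth limits every number of peaks.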

Other observations

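All counts and tests in this part were chosen after the data were seen.

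PRMT1 in control hTSC was more frequent at tRNA genes than at coding genes. A control peak lay at 27.99% of tRNA genes (95% CI 23.9 to 32.4%), against 8.84% of coding genes (odds ratio 4.01, Fisher's exact test p = 1.92e-30). Outside the dense tRNA and histone region at 25 to 35 Mb of chromosome 6, the share was 28.1% (84 of 299). A peak of 2639 bp on chromosome 17 covered TRW-CCA1-1, TRG-TCC3-1, TRD-GTC2-11 and TRP-CGG1-3. Of the 124 tRNA genes with PRMT1, 108 also had H4R3me2a and 118 had RNA polymerase II in control cells. Neighbouring tRNA genes share peaks, so these genes are not independent. Across all tRNA genes, H4R3me2a was present at 219 in control and 187 after knockdown, and RNA polymerase II at 239 and 134. RNA polymerase II does not transcribe tRNA genes, which RNA polymerase III does, so these peaks describe what lies within 1 kb of them.

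Genes for snRNA, a class that includes the RNA parts of the splicing machinery, had control PRMT1 peaks at 14.3% (95% CI 9.17 to 20.8%). The odds ratio against coding genes was 1.72 (Fisher p = 0.0227). The U5 genes RNU5E-1 (1332 bp) and RNU5D-1 (1153 bp) were among them. RNA polymerase II at snRNA genes was present at 51 in control and 43 after knockdown. Other non-coding classes had PRMT1 less often than coding genes, with 42 of 1911 microRNA genes (odds ratio 0.232, Fisher p = 4.05e-31), 19 of 1196 snoRNA genes (odds ratio 0.167, Fisher p = 2.28e-25) and 527 of 18177 long non-coding RNA genes (odds ratio 0.308, Fisher p = 6.95e-139). At short genes, such as those for microRNA and snoRNA, the windows at both ends nearly coincide. Less sequence was therefore searched there than at longer coding genes, and these odds ratios do not adjust for it. Among the long non-coding RNA genes, LINC00324 shared the chromosome 17 tRNA peak and HEXIM2-AS1 the 2483 bp peak by HEXIM1.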
